A study of Mus musculus with 12 samples.

How the data were processed

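RNA was measured in 12 libraries of NRAS/AE9a leukemic cells, mouse acute myeloid leukemia cells that, by their name, carry NRAS and AML1-ETO9a. Per the labels, the cells were wild type (WT) or Tet2 knockout (KO). Actinomycin D, an inhibitor of transcription, was given at a dose of 5 µg/ml for 0, 4 or 8 h, with 2 libraries in each of the 6 groups. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Genotype also cannot be separated from any other difference between the WT and KO cells, since the labels name no second line of either genotype.

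The deposited values are TPM per gene, a gene's length-corrected share of the transcripts of a library, 1 column per library. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. Per the labels, reads were paired-end. The submitters' processing notes name STAR, RSEM and the mm10 genome, and their versions, the annotation and the strand setting are not given in the sources used here. Each column summed to 1000000 within 1, so the values are shares of a library, sequencing depth is unknown, and no interval from counting could be given. No added RNA standard is named in the labels. All changes after actinomycin D are therefore relative to the other transcripts of the library, and a transcript lost more slowly than the rest gains TPM.

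The table held 24589 genes, of which 8737 were at 0 in every library and 27 had a name that had been turned into a date. The 11152 genes with at least 1 TPM in at least 2 libraries were tested. Of these, 19 had a date as name and were left out of the named genes. TPM were used as deposited on the log2(TPM + 1) scale, which understates the change of low genes. Linear models of limma 3.58.1 in R 4.3.3 had 1 mean per group over all 12 libraries, 6 residual degrees of freedom and an empirical Bayes spread with a trend on mean expression. Contrasts were KO against WT at 0 h, 4 h and 8 h against 0 h in each genotype, and the difference of these changes between genotypes. A further model had a straight line on hours for each genotype, with 8 residual degrees of freedom, and tested the difference of the slopes, given over 8 h. With equally spaced times its estimate equals the 8 h difference, while its spread also contains departures from a line. Adjusted p are Benjamini-Hochberg values from limma with a threshold of 0.05, and errors are standard errors (SE) unless given as SD.

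Lists of genes were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The 24 lists were writers, readers and erasers of 5-methylcytosine in RNA, the m6A machinery, homing and adhesion, stemness, myeloid differentiation, immediate early and short-lived transcripts, long-lived housekeeping transcripts, cytosolic ribosomal proteins, mitochondrial mRNA, nuclear oxidative phosphorylation, glycolysis, Zfp zinc fingers, replication, mitosis, p53 targets, interferon-stimulated genes, the unfolded protein response, cholesterol synthesis, and markers of T and NK cells, B cells, erythroid cells, mast cells and basophils, megakaryocytes, and stroma and endothelium. The mitochondrial pattern matched 0 gene names. The 20 lists with at least 5 measured members were tested with camera of limma at a preset correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation. A camera direction is therefore relative to the other genes and can differ in sign from a list's median. Named genes were Tet2, Tspan13, Cxcr4 and Ybx1 in every comparison, and the largest changes past the threshold. These were 10 each way for KO against WT at 0 h, WT at 8 h and the slopes, and 3 each way in other comparisons. They had a mean of at least 5 TPM, and between 2 groups no overlap of their libraries, so that both libraries of each group show the direction. Symbols that start with Gm and a digit or end in Rik were left out. Of each list, members were named from the 4 with the smallest p, and any other named gene was chosen after its values were seen. Where no gene passed, the 5 with the smallest p are given. Genes with near-identical copies, pseudogenes and multicopy histone genes are uncertain, since RSEM may split their reads.

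Alternatives were median-ratio scaling, scaling to the housekeeping list, no filter, a mean of at least 5 TPM, pseudocounts of 0.1 and 0.5, limma without the trend, an added 2-fold limit, the replicate number as a block, a fit of the compared groups alone and leaving out each library. Chosen after the data were seen were removal of a trend on transcript length, transcripts of at least 1000 nt, and a robust spread. Transcript lengths, 3' untranslated regions (UTRs) and positions came from GENCODE M21 on GRCm38, the assembly of mm10, by gene symbol, and 97.3% of tested genes had a match. The authors' annotation may differ.

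The models were tested on simulated data over the 11152 genes with 200 changed. The changed genes were drawn from those whose mean log2(TPM + 1) lay above that of 5 TPM. Recovery of lower genes was not measured. For KO against WT at 0 h, 59.7%, 98.2% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, and 8.2% of calls were false. For the 8 h difference these shares were 15.4%, 84.6% and 97.1%, with 15.3% false, above the nominal level, and the cause was not tested. For the slope difference they were 0%, 23.9% and 71.4%, with 0% false. Small differences in slope were therefore not detectable with this model, although the 8 h difference recovered more in the same design.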

Results

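RNA was measured in 12 libraries of NRAS/AE9a leukemic cells from the mouse, WT or Tet2 KO, at 0, 4 and 8 h of actinomycin D, with 2 libraries per group. The series asks how TET2, an enzyme that oxidises 5-methylcytosine, acts on mRNA in leukemia stemness and homing. The sequencing depth is unknown, since values are TPM. Between 9093 and 10827 genes had at least 1 TPM in a library. The 2 libraries of a group correlated across genes with a Pearson r of 0.991 to 0.994, and libraries of different groups with at most 0.974. The first principal component held 80.7% of the variance and the second held 10.6%. The 10 most abundant genes took 22.0% and 17.8% of the TPM in the WT libraries at 0 h, and 13.4% and 13.4% in the KO libraries at 0 h.

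Tet2 mRNA was still present in the KO cells. It had 13.05 and 16.03 TPM in the WT libraries at 0 h, 10.6 and 10.2 at 4 h, and 5.66 and 6.46 at 8 h. In the KO libraries it had 10.2 and 10.2 TPM at 0 h, 6.42 and 5.82 at 4 h, and 4.32 and 4.52 at 8 h. Tet2 at 0 h was lower in KO by a log2 change of -0.47 ± 0.13 (SE, n = 2 against 2, limma adjusted p = 0.0167). That call was lost without WT 0 h replicate 2 (adjusted p = 0.105), KO 0 h replicate 1 (0.0928) or KO 0 h replicate 2 (0.0964), in a range of 0.00402 to 0.105 over 23 alternatives. A gene-level TPM does not show which exons a knockout removed, so it checks the genotype only weakly. Tet2 lies on the minus strand of chromosome 3 from 133463679 to 133545139 (GRCm38).

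The comparison of KO with WT cells at 0 h asks what the leukemic cells express before transcription is blocked. Chil3, a chitinase-like protein of myeloid cells, had 633 ± 9.02 TPM (SD, n = 2) in WT and 34.5 ± 0.502 in KO cells, a log2 change of -4.16 ± 0.09 (SE). Also lower in KO were Slfn4, a Schlafen family gene, by -4.06 ± 0.10, and Camp, the antimicrobial peptide cathelicidin of neutrophil granules, by -3.48 ± 0.15. The mast cell chymase Cma1 was lower by -3.21 ± 0.13 and the carbonic anhydrase Car4 by -3.13 ± 0.14. The interferon-induced genes Oasl2 (-2.86 ± 0.12), Oas1g (-2.79 ± 0.19), Isg15 (-2.76 ± 0.45) and Rtp4 (-2.71 ± 0.23) were lower too. Mcpt4, another mast cell protease, had a mean of 6.19 TPM in WT and was listed at 0 in both KO libraries. Higher in KO were Igfbp7, a secreted protein that binds insulin-like growth factors, by 3.15 ± 0.13, with 1.20 TPM in WT and 18.5 in KO cells, and the carbonic anhydrase Car2 by 2.65 ± 0.18. Gzmb, which encodes granzyme B, rose by 2.51 ± 0.19 and Angpt1, the TIE2 ligand angiopoietin 1, by 2.38 ± 0.12. Npl rose by 2.35 ± 0.09, the collagen Col18a1 by 2.22 ± 0.12, and Mpo, the myeloperoxidase of granulocyte precursors, by 2.16 ± 0.12. Hbb-b2 and Hbb-bt, both at 2.57 ± 0.09, had identical estimates and are adult beta-globin paralogs whose reads may be shared, so each is uncertain. Tmem254b (2.83 ± 0.84, adjusted p = 0.0272) is also uncertain, as its call was lost in 8 of 23 alternatives with a range of 1.9e-68 to 0.141, and its estimate was 4.84 without WT 0 h replicate 1 and 0.81 without replicate 2.

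In all, 2871 of 11152 genes passed the threshold at 0 h, 1593 higher and 1278 lower in KO. The median log2 change of all genes was 0.06. Without KO 0 h replicate 1 the count was 1703, with 807 higher and 896 lower, and without KO 0 h replicate 2 it was 1678, with 837 higher and 841 lower. Without WT 0 h replicate 1 it was 2254, with 972 higher and 1282 lower, and 1668 were higher and 824 lower without WT 0 h replicate 2, so the balance of directions rested on single libraries.

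Interferon-stimulated genes were lower in KO at 0 h in 31 of 36 measured members and higher in 1, and adjusted over the list alone 33 were lower and 1 higher. The members with the smallest p were Oasl2, Oas3 (-2.27 ± 0.10), Oas1a (-1.88 ± 0.09) and Oas2 (-2.64 ± 0.13), which encode 2'-5'-oligoadenylate synthetases or a related protein. The list median was -1.39 (camera adjusted p = 2.6e-28, and adjusted p = 0.00686 with an estimated correlation). Of 38 myeloid differentiation genes 30 were lower and 3 higher, and adjusted over the list alone 31 and 3, with a median of -0.81 (camera adjusted p = 3.7e-21, and adjusted p = 0.0277 with an estimated correlation). The granule protein Ngp was lower by -2.33 ± 0.08 and the GM-CSF receptor chain Csf2ra by -2.41 ± 0.08. After median-ratio scaling 30 interferon-stimulated and 29 myeloid genes were lower.

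Cytosolic ribosomal protein genes were higher in KO at 0 h in 76 of 83 and lower in 1, and adjusted over the list alone in 79 and 1, with a median of 0.38. An example was Rpl28 at 0.48 ± 0.06 (camera adjusted p = 2.7e-24 for the list, and adjusted p = 0.000584 with an estimated correlation). The number higher was 67 after median-ratio scaling and 43 after scaling to the housekeeping list. Nuclear genes of oxidative phosphorylation were higher in 41 of 89 and lower in 0, and adjusted over the list alone 49 were higher and 1 lower, with a median of 0.27 and Atp5g1 at 0.47 ± 0.08. Their camera adjusted p was 1.7e-08, and adjusted p = 0.0502 with an estimated correlation. With median-ratio scaling 24 were higher, and with housekeeping scaling 8 were higher and 2 lower. With 1 library left out, the number higher ranged from 61 to 78 for ribosomal protein and from 18 to 47 for oxidative phosphorylation genes. Both lists hold short transcripts, with median lengths of 794 and 850 nt. All genes under 600 nt had a median of 0.23 in KO against WT at 0 h, with a gap to longer genes of 0.167, and the 2 WT 0 h libraries differed by a gap of 0.25. Beside the 50 other genes nearest in length to each member, whose median was 0.15 for both lists, 79 of 83 ribosomal protein and 67 of 88 oxidative phosphorylation genes lay higher. With the length trend removed 61 and 24 were higher, with medians of 0.28 and 0.16. Both length checks were chosen after the results were seen.

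Stemness genes were higher in KO at 0 h in 13 of 22 and lower in 3, and adjusted over the list alone in 14 and 3 (median 0.47, camera adjusted p = 0.00102, and adjusted p = 0.146 with an estimated correlation). With 1 library left out 7 to 14 were higher. Besides Angpt1, the transcription factors Gfi1b and Gata2 were higher by 1.74 ± 0.15 and 1.35 ± 0.15, and the progenitor surface protein Cd34 by 0.83 ± 0.08. Gata2 is also in the mast cell and basophil list, so the lists overlap. Only 22 of 33 listed stemness genes and 5 of 15 listed erythroid markers were measured. Erythroid markers were higher in 4 of 5, and adjusted over the list alone 4 were higher and 1 lower (camera adjusted p = 0.0011, and adjusted p = 0.146 with an estimated correlation), among them Gata1 at 0.86 ± 0.19 and the transferrin receptor Tfrc at 0.66 ± 0.07. Megakaryocyte markers were higher in 3 of 7 (camera adjusted p = 0.0414, and adjusted p = 0.366 with an estimated correlation), with the integrin Itga2b at 2.13 ± 0.09. Mast cell and basophil markers went both ways, 6 higher and 5 lower of 12, and likewise adjusted over the list alone (camera adjusted p = 0.696). Cpa3 at 1.71 ± 0.08 and Mcpt8 at 1.56 ± 0.09 were higher, against the lower Cma1 and Mcpt4. Of markers of other cell types, Nkg7 of T and NK cells was the only one measured of its list and was higher by 1.28 ± 0.28. No B cell marker was measured. Of 3 stromal and endothelial markers, Pdgfrb (1.08 ± 0.17) and Thy1 (0.44 ± 0.09) were higher and Fn1 (-0.89 ± 0.16) was lower.

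Homing and adhesion genes had 6 higher and 8 lower of 37 at 0 h, and likewise adjusted over the list alone (camera adjusted p = 0.198). The number lower was 12 after median-ratio and 16 after housekeeping scaling, and with 1 library left out 3 to 7 were higher and 5 to 11 lower. The integrin chains Itgam (-1.05 ± 0.08) and Itgb2 (-1.02 ± 0.08) and the tetraspanin Cd9 (-0.96 ± 0.08) were lower, and Itgb7 (1.12 ± 0.11) was higher. Of 19 genes of RNA 5-methylcytosine 4 were higher and 1 lower, and likewise adjusted over the list alone (camera adjusted p = 0.245), and with 1 library left out 3 to 6 and 0 to 1. The methyltransferase Nsun2 was higher by 0.52 ± 0.07 and the Y-box protein Ybx3 by 0.49 ± 0.08. Of 17 m6A genes 1 was higher, Mettl16 at 0.42 ± 0.12, and 0 adjusted over the list alone (camera adjusted p = 0.4) or without WT 0 h replicate 1 or either KO 0 h library. Immediate early genes had 10 higher and 16 lower of 48, and adjusted over the list alone 10 and 18 (camera adjusted p = 0.0915), and with 1 library left out 5 to 11 were higher and 6 to 18 lower. Housekeeping genes had 14 higher and 5 lower of 30, and likewise adjusted over the list alone (camera adjusted p = 0.0897), and with 1 library left out 9 to 17 were higher. Glycolysis genes had 5 higher and 1 lower of 19, and adjusted over the list alone 5 and 2. Without WT 0 h replicate 1 they had 4 higher and 4 lower, and over the libraries left out 3 to 7 and 0 to 4. Their median was -0.02 while the camera direction was up (adjusted p = 0.549). Zfp genes had 4 higher and 14 lower of 266, and 0 adjusted over the list alone, and with 1 library left out 0 to 4 higher and 5 to 14 lower, with a median of 0.01 and a camera direction of down (adjusted p = 0.428).

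Replication genes had 0 of 29 past the threshold at 0 h, and 0 adjusted over the list alone (camera adjusted p = 0.143). Mitosis genes had 2 higher of 29, Cdk1 at 0.28 ± 0.08 and Ect2 at 0.38 ± 0.11, and 0 adjusted over the list alone (camera adjusted p = 0.0915). For p53 targets 4 were higher and 2 lower of 22, and adjusted over the list alone 5 and 3 (camera adjusted p = 0.425). Genes of the unfolded protein response had 6 higher and 1 lower of 22, and adjusted over the list alone 7 and 1 (camera adjusted p = 0.0915). Cholesterol synthesis genes had 4 higher and 1 lower of 21, and adjusted over the list alone 6 and 1 (camera adjusted p = 0.0897). These small counts rested on single libraries. Without WT 0 h replicate 1 they were 1 higher for mitosis, 1 higher and 2 lower for p53 targets, and 1 higher and 1 lower for each of the unfolded protein response and cholesterol synthesis. With any 1 library left out the number higher ranged from 0 to 5, 1 to 5, 1 to 10 and 1 to 6 in the same order.

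**Figure D1:**
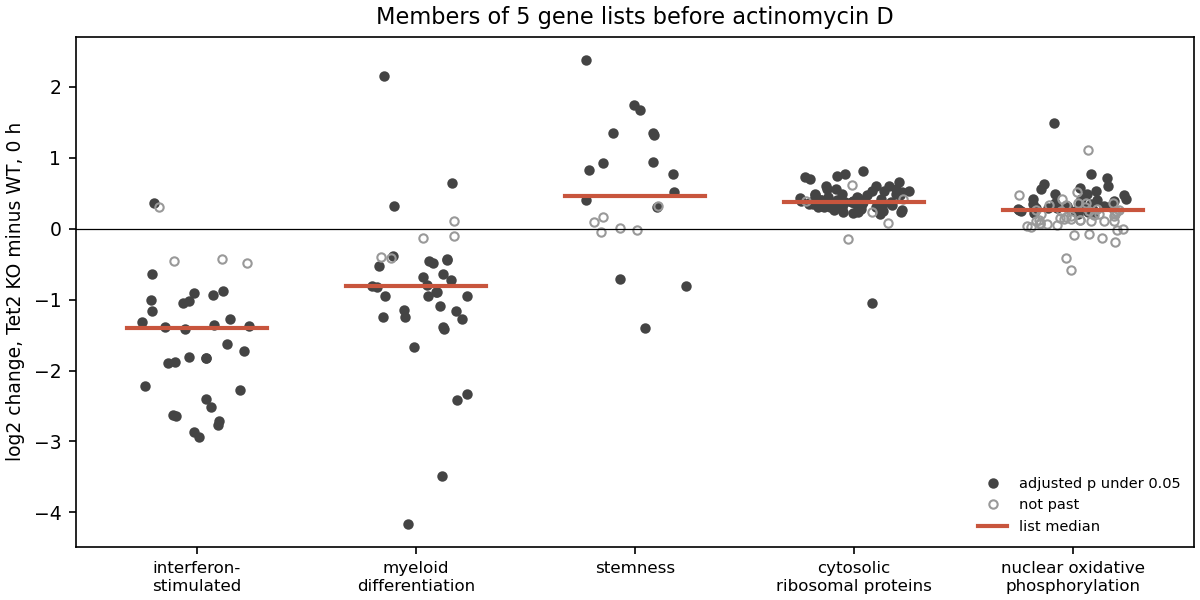
Each point is the log2 change of TPM + 1 between KO and WT cells at 0 h for 1 member of 5 gene lists, filled where its adjusted p was under 0.05, and the horizontal lines are list medians. Interferon-stimulated genes had a median of -1.39 and myeloid differentiation genes of -0.81, while ribosomal protein genes lay at 0.38.

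In WT cells, 8 h of actinomycin D left the deepest relative loss in Kpna2, a nuclear import factor, which went from 409 ± 31.8 TPM (SD, n = 2) to 6.68 TPM, a log2 change of -5.74 ± 0.08 (SE). The chaperone Hspa8 fell by 5.31 ± 0.08, from 3188 to 79.3 TPM, and the mitotic kinase Plk1 by 5.28 ± 0.17. Next came Chst12 (-5.26), the stress-response transcription factor Nfe2l2 (-5.24), Samsn1 (-5.01), Vapa (-4.99), the cyclin Ccna2 (-4.83), and the transcription factors Gfi1 (-4.81) and Nfe2 (-4.79). The largest relative gain was in Rpph1, the RNA of RNase P, from 173 ± 51.7 to 5939 ± 1805 TPM (log2 5.09 ± 0.20). Rpph1 is annotated as a ribozyme and not as an mRNA, while the libraries were made with an mRNA kit, so its gain is uncertain. Mast cell proteases rose as a share, Cma1 by 3.07 ± 0.13, Mcpt4 by 2.75 ± 0.17 and Tpsb2 by 2.55 ± 0.13. The chemokines Ccl12 (2.42) and Ccl5 (2.35), Wfdc17 (2.41), the MHC class II chain H2-Aa (2.36) and the noncoding Epb41l4aos (2.26) rose as well. Hist1h4h (2.28, adjusted p = 0.0069) is a multicopy histone gene and uncertain, as its call was lost without WT 0 h replicate 1 (adjusted p = 0.13) and with a robust spread (0.0543), in a range of 1.8e-29 to 0.13. Its estimate was 0.94 without that library and 3.63 without WT 0 h replicate 2.

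At 8 h in WT cells 9890 genes passed the threshold, 946 higher and 8944 lower, around a median of -1.40 over all genes. After median-ratio scaling, which sets that typical loss to about 0, 8749 passed, 4247 higher and 4502 lower. At 4 h in WT cells 8671 passed, 755 higher and 7916 lower, around a median of -0.81, and 4112 higher and 3885 lower after median-ratio scaling. At 4 h the deepest losses were in Irf2bp1 (-4.25 ± 0.16), the noncoding snoRNA host Gas5 (-4.20 ± 0.18) and the transcription regulator Cited2 (-4.18 ± 0.10). The largest gains at 4 h were uncertain. Apoo-ps, a pseudogene, had 2.37 ± 0.97 (adjusted p = 0.0401, lost in 8 of 23 alternatives, range 3.4e-33 to 0.317), with 1.38 and 3.35 without WT 0 h replicate 1 and 2. The multicopy histone Hist1h3h had 1.65 ± 0.50 (0.00912, lost in 3, range 7.3e-19 to 0.0844). Epb41l4aos had 2.00 ± 0.51 (0.00331, lost in 1, range 2.2e-25 to 0.0646).

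Gene groups in WT cells at 8 h parted from each other, and counts adjusted over the list alone were the same as those over all genes unless given. Mitosis genes were lower in 29 of 29 (median -3.37, camera adjusted p = 5.9e-06, and adjusted p = 0.356 with an estimated correlation), with the kinase Cdk1 at -2.87 ± 0.08 and the kinesin Kif11 at -4.26 ± 0.10. Replication genes were lower in 29 of 29 (median -2.30, 0.000917, and adjusted p = 0.451 with an estimated correlation), with Cdt1 at -3.75 ± 0.11. The m6A genes were lower in 17 of 17 (median -2.72, 0.0309, and adjusted p = 0.451 with an estimated correlation), with the reader Ythdf1 at -3.58 ± 0.14. Zfp genes were lower in 263 of 266 (median -1.75, 0.00458, and adjusted p = 0.512 with an estimated correlation). Cholesterol synthesis genes were lower in 21 of 21 (median -1.56, 0.0369, and adjusted p = 0.617 with an estimated correlation), but 8 were higher and 8 lower after median-ratio scaling. That scaling left 27 mitosis, 21 replication, 13 m6A and 194 Zfp genes lower.

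Ribosomal protein genes were higher in WT at 8 h in 59 of 83 and lower in 12 (median 0.34, camera adjusted p = 4.7e-38, and adjusted p = 0.000149 with an estimated correlation), and higher in 79 after median-ratio scaling. Rplp2 rose by 1.06 ± 0.09, while Rpl7l1 fell by 1.63 ± 0.10. Oxidative phosphorylation genes had 36 higher and 33 lower of 89 (median 0.04), above the typical gene by camera (adjusted p = 1.8e-17, and adjusted p = 0.0152 with an estimated correlation), and 80 higher and 5 lower after median-ratio scaling. Megakaryocyte markers were higher in 5 of 7 (median 0.93, 9.1e-10, and adjusted p = 0.0237 with an estimated correlation), with the chemokine Pf4 at 2.02 ± 0.14. Mast cell and basophil markers were higher in 8 and lower in 4 of 12 (median 1.31, 3.3e-09, and adjusted p = 0.0548 with an estimated correlation), with the transcription factor Gata2 at -3.25 ± 0.15. Housekeeping genes were higher in 12 and lower in 14 of 30, with a median of -0.11 but up by camera (3.7e-08, and adjusted p = 0.449 with an estimated correlation). After median-ratio scaling 26 were higher and 3 lower, with a median of 1.60. Ferritin Ftl1 rose by 1.73 ± 0.06 and Actb fell by 2.16 ± 0.07. Erythroid markers were higher in 1 and lower in 1 of 5, up by camera (0.00482, and adjusted p = 0.292 with an estimated correlation). After median-ratio scaling 4 erythroid, 7 megakaryocyte and 11 mast cell markers were higher, and 0, 0 and 1 lower. Myeloid genes were higher in 10 and lower in 25 of 38, with a median of -0.71 but up by camera (0.0115, and adjusted p = 0.493 with an estimated correlation). Their split turned to 22 higher and 14 lower after median-ratio scaling, and Prtn3 fell by 3.07 ± 0.07.

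For the other lists at 8 h in WT, camera made no call. Genes of RNA 5-methylcytosine were lower in 18 of 19 and higher in 1 (camera adjusted p = 0.216), with Alyref at -3.25 ± 0.10. Homing genes were higher in 7 and lower in 27 of 37 (0.347), with the chemokine receptors Cxcr2 at -4.08 ± 0.13 and Ccr1 at -3.30 ± 0.09. Stemness genes were higher in 2 and lower in 17 of 22 (0.753), with Myc at -4.73 ± 0.14, Myb at -3.78 ± 0.10 and Ly6a at 2.16 ± 0.07. Immediate early genes were higher in 2 and lower in 42 of 48 (0.145). Glycolysis genes were higher in 3 and lower in 12 of 19, and adjusted over the list alone 3 and 11 (0.218). For p53 targets 20 of 22 were lower (0.386). Interferon-stimulated genes were higher in 2 and lower in 27 of 36 (0.511), with Bst2 at 1.58 ± 0.07. Genes of the unfolded protein response were higher in 3 and lower in 15 of 22 (0.218), with Xbp1 at -4.40 ± 0.09. After median-ratio scaling most changed members were higher for homing (22 higher, 11 lower), interferon-stimulated (16 and 11), glycolysis (13 and 4) and unfolded protein response genes (15 and 6). The lists of 5-methylcytosine (6 higher, 7 lower), p53 targets (8 and 8), stemness (6 and 11) and immediate early genes (14 and 25) were then split as well.

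**Figure D2:**
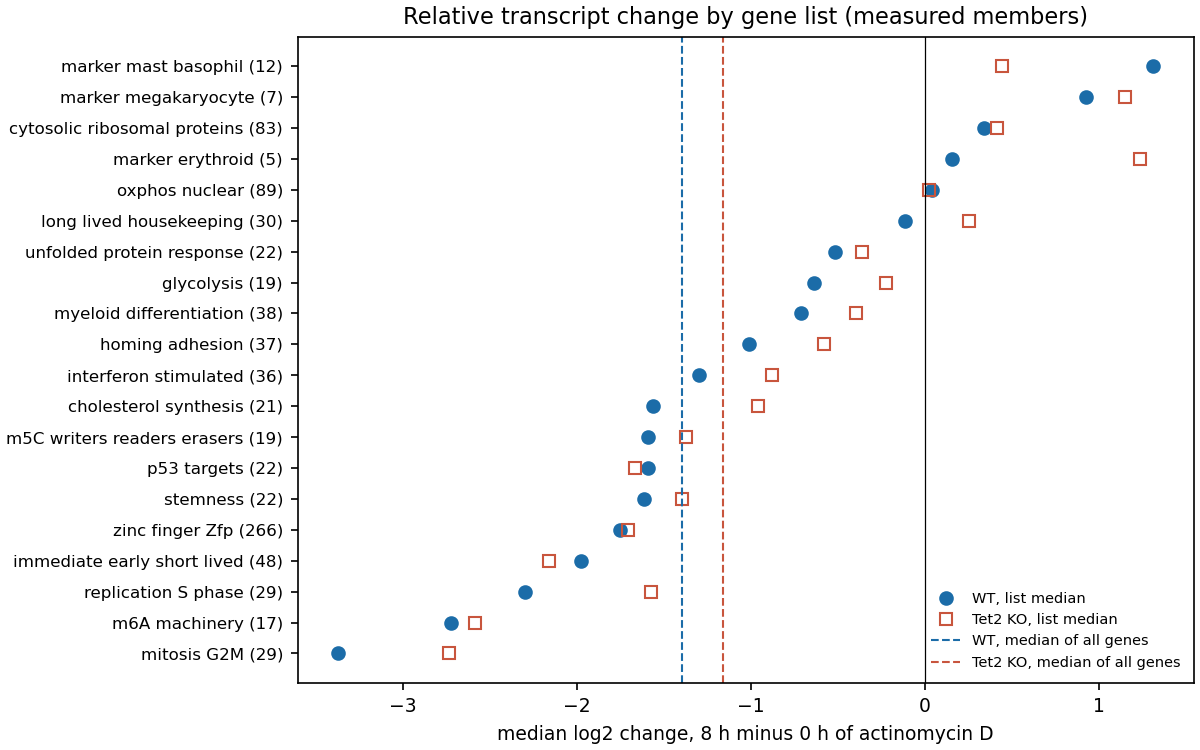
Points are the median log2 change of TPM + 1 from 0 h to 8 h of actinomycin D for each gene list, filled for WT and open for KO, with the measured members in parentheses. Dashed lines mark the median of all genes, -1.40 in WT and -1.16 in KO, below which lie the mitosis genes at -3.37 and -2.73.

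In KO cells the deepest relative losses at 8 h were in Samsn1 (-5.31 ± 0.17) and Cited2 (-5.28 ± 0.10), and the largest gain was in Rpph1 (3.39 ± 0.20). The gain of Rpph1 is uncertain here for the same reason as in WT. The pseudogene Atp6v0c-ps2 had a mean of 59.6 TPM in KO at 0 h and was listed at 0 in both KO libraries at 8 h, and is uncertain. Hbb-y (2.57 ± 1.06, adjusted p = 0.0386, range 0.0104 to 0.216) and Apoo-ps (2.51 ± 0.97, 0.0281, range 0.000916 to 0.348) are uncertain too, since each call was lost in 8 of 23 alternatives. With 1 library left out their estimates ranged from 1.72 to 3.42 for Hbb-y and from 0.92 to 4.10 for Apoo-ps. At 4 h in KO cells Cited2 (-5.32 ± 0.10), the oncogene Myc (-5.03 ± 0.14) and the NF-kappaB inhibitor Nfkbia (-4.92 ± 0.13) fell most. Dpm1 (1.09 ± 0.15) and Ccl12 (1.09 ± 0.24) rose, as did Epb41l4aos (1.89 ± 0.51, adjusted p = 0.00524), whose call was lost at 0.95 without KO 0 h replicate 2 (0.0674, range 9e-05 to 0.0674). At 8 h 9469 genes passed, 1064 higher and 8405 lower, around a median of -1.16, and at 4 h 8123, 544 higher and 7579 lower, around a median of -0.70. After median-ratio scaling the split at 8 h was 4382 higher and 4480 lower, and at 4 h 4172 and 3816. Mitosis genes were lower in 29 of 29 and replication genes in 28 of 29 at 8 h, and ribosomal protein genes higher in 61 and lower in 4 of 83, each likewise adjusted over the list alone. After median-ratio scaling mitosis genes were higher in 2 and lower in 26, replication genes higher in 10 and lower in 13, and ribosomal protein genes higher in 81 and lower in 0. At 8 h 8198 genes were lower in both genotypes and 737 higher in both. The 8 h changes of the genotypes correlated across genes, which are not independent replicates, with a Pearson r of 0.926 and a Spearman rho of 0.937.

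The difference between genotypes in the change after actinomycin D asks whether relative transcript loss differs with genotype. It reflects stability only if transcription was blocked alike in WT and KO cells, which was not tested. At 8 h mitosis genes were higher in KO relative to their start than in WT, in 22 of 29 members and 23 adjusted over the list alone, with a median difference of 0.72. Examples were the topoisomerase Top2a (1.14 ± 0.12), Birc5 (0.83 ± 0.10), the mitotic activator Cdc20 (1.34 ± 0.16) and the cyclin Ccnb2 (0.87 ± 0.11). Replication genes were higher in 15 of 29, and 19 adjusted over the list alone, with the helicase subunit Mcm6 at 1.29 ± 0.12 and the ribonucleotide reductase subunits Rrm1 and Rrm2 at 0.99 ± 0.11 and 0.91 ± 0.12. Lower in KO were 10 of 48 immediate early genes, likewise adjusted over the list alone, with Nfkbia at -1.16 ± 0.18, Dusp5 at -1.53 ± 0.32 and Junb at -0.67 ± 0.12. Mast cell markers were lower in 5 of 12, likewise adjusted over the list alone, among them Tpsb2 at -1.10 ± 0.19 and Cma1 at -0.94 ± 0.19. Mcpt4 of this list was at 0 in both KO libraries at 0 h. Changes of such low genes are understated by log2(TPM + 1), so starting levels may contribute to this list's difference. After median-ratio scaling 17 mitosis and 13 replication genes were higher, and 25 immediate early and 10 mast cell genes lower. Homing genes were higher in 13 and lower in 1 of 37, but in 10 and 8 after median-ratio scaling. Genes of RNA 5-methylcytosine were higher in 7 and lower in 0 of 19, and in 4 and 1 after that scaling. Ribosomal protein genes were higher in 27 and lower in 8 of 83, but in 3 and 8 after that scaling. With 1 library left out the ranges were 18 to 22 mitosis and 14 to 18 replication genes higher, and 5 to 12 immediate early and 4 to 6 mast cell genes lower. The 5 immediate early genes were found without WT 0 h replicate 1, and housekeeping scaling gave 22.

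By size of the 8 h difference, Tmem176a was higher in KO by 1.62 ± 0.30. Cox4i2 (1.62 ± 0.46, adjusted p = 0.0282) lost its call in 8 of 23 alternatives (range 0.0132 to 0.111), and Oaz1-ps (1.58 ± 0.30) is a pseudogene, so both are uncertain. The pseudogene Atp6v0c-ps2 and the antisense RNA Rab26os had means of 1073 and 16.9 TPM in WT at 8 h and were listed at 0 in both KO libraries, and are uncertain. The multicopy histone Hist2h3b (-3.48 ± 0.84, adjusted p = 0.0136) lost its call in 4 of 23 alternatives (range 0.00165 to 0.085). In all 2222 genes passed at 8 h, 1929 higher in KO and 293 lower, with a median difference of 0.18 over all genes. The balance changed with the scaling, to 986 higher and 894 lower after median-ratio scaling and 773 higher and 804 lower after housekeeping scaling. Median-ratio scaling centres the libraries, and the housekeeping list itself had a median 8 h difference of 0.23, near that of all genes. Either scaling thus removes most of the general shift, so these splits do not decide on its source. Without WT 0 h replicate 2 the count was 1409, without KO 0 h replicate 1 it was 1323, and without KO 0 h replicate 2 it was 1203.

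At 4 h 10 of 48 immediate early genes were lower in KO relative to their start than in WT, and 27 adjusted over the list alone, with a median difference of -0.63. The number lower was 19 after median-ratio and 18 after housekeeping scaling, but 3 without WT 0 h replicate 1, and 2 to 12 over the libraries left out. Id1, an inhibitor of helix-loop-helix factors, had -1.49 ± 0.15 (adjusted p = 0.0012) and was called under each of 24 alternatives (range 8.8e-05 to 0.0249). Ddit4 had -1.46 ± 0.20 (adjusted p = 0.0123, lost in 3, range 0.00324 to 0.0715) and Socs1 -1.83 ± 0.31 (0.0264, lost in 9, range 0.00548 to 0.136). The helicase-like Znfx1 had 1.13 ± 0.16 (0.0123, lost in 4, range 0.00357 to 0.0726) and Hspa8 0.69 ± 0.11 (0.0201, lost in 7, range 0.00357 to 0.0951). In all 39 genes passed, 6 higher and 33 lower. That count moved to 19 and 98 without WT 0 h replicate 1 or 2, 24 and 14 without WT 4 h replicate 1 or 2, 10 and 9 without KO 0 h replicate 1 or 2, and 14 and 13 without KO 4 h replicate 1 or 2.

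With a straight line through the 3 times of each genotype, 0 genes differed in slope by limma, with 1683 at an unadjusted p under 0.05, and limma without the trend and with a robust spread also gave 0. In simulated data this model recovered 0%, 23.9% and 71.4% of genes changed by 0.5, 1 and 2 on the log2 scale. The 8 h difference recovered 15.4%, 84.6% and 97.1%, so 0 genes does not show that loss was alike. The 5 genes with the smallest p, each at an adjusted p of 0.0522, were Bin2 (1.12 ± 0.17), Ppp6r1 (0.82 ± 0.13), Nadk (0.80 ± 0.13), Atp11b (0.98 ± 0.16), and Mcpt4, which was listed at 0 in both KO libraries at 0 h. Each of the first 4 passed in 5 of 23 alternatives and Mcpt4 in 4, in ranges that together span 0.000757 to 0.634. The count was 26 with no filter, 32 with a mean of at least 5 TPM, 33 with a pseudocount of 0.5, 30 with transcripts of at least 1000 nt, a limit chosen after the data were seen, and 1 with median-ratio scaling. Without WT 0 h replicate 1 the count was 288. Adjusted over the list alone, 16 mitosis, 9 replication, 9 homing, 3 myeloid and 3 cholesterol synthesis genes had a higher slope in KO, and 1 mast cell gene a lower one. A higher slope in KO was also found for 2 glycolysis and 2 erythroid genes. The same held for 1 gene each of the 5-methylcytosine, stemness and p53 lists, while the other lists had 0. Camera called mast cell markers down (adjusted p = 3.6e-07, and adjusted p = 0.21 with an estimated correlation), among them Mcpt4 with its start at 0 in KO. It called mitosis genes up (1.0e-06, and adjusted p = 0.21 with an estimated correlation). It called immediate early genes down (1.2e-06, and adjusted p = 0.711 with an estimated correlation) and replication genes up (4.0e-05, and adjusted p = 0.651 with an estimated correlation). Oxidative phosphorylation genes were down by camera at a median of 0.07 (0.00112, and adjusted p = 0.711 with an estimated correlation), and Zfp genes at a median of 0.03 (0.00112, and adjusted p = 0.879 with an estimated correlation). Among lists without a call, 0.19 was the ribosomal protein median, yet the camera direction was down (adjusted p = 0.409). The same difference in sign was found for interferon-stimulated (median 0.19, camera adjusted p = 0.579) and stemness genes (0.15, 0.579). It was also found for myeloid genes (0.14, 0.579) and p53 targets (0.02, 0.337).

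Tspan13, a tetraspanin, had 2.59 ± 0.446 TPM (SD, n = 2) in WT and 9.24 ± 0.417 in KO cells at 0 h, a log2 change of 1.52 ± 0.21 (SE, adjusted p = 2e-04). At 8 h it had 2.17 ± 1.11 TPM in WT and 11.5 ± 1.43 in KO, and neither change from 0 h passed (adjusted p = 0.326 and 0.214). The change in KO passed after median-ratio scaling (1.58, adjusted p = 6.6e-05, range 6.6e-05 to 0.549), and that in WT without WT 8 h replicate 2 (-0.58, 0.00854) and, in the other direction, after median-ratio scaling (0.96, 0.00208), in a range of 0.00208 to 0.873. Its 8 h difference of 0.50 ± 0.29 did not pass (adjusted p = 0.257), but did without WT 8 h replicate 2 (0.87, adjusted p = 0.021, range 0.021 to 0.734), and was 0.14 without WT 8 h replicate 1. Cxcr4, the chemokine receptor of homing to bone marrow, had 109 ± 17.7 TPM in WT and 69.7 ± 2.28 in KO at 0 h, a change of -0.63 ± 0.14 (adjusted p = 0.00585). That call was lost without WT 0 h replicate 2 (adjusted p = 0.0597) or KO 0 h replicate 2 (0.0506), in a range of 6.3e-07 to 0.0597. Cxcr4 fell by 3.93 ± 0.14 in WT and fell by 4.27 ± 0.14 in KO cells over 8 h. The difference of -0.34 ± 0.20 did not pass (adjusted p = 0.265), but did with median-ratio scaling (-0.65, adjusted p = 0.0196), housekeeping scaling (-0.58, 0.029) and the length trend removed (-0.55, 0.0441), in a range of 0.0196 to 0.578, and was -0.18 without WT 0 h replicate 1. Ybx1, a Y-box protein that binds RNA, had 734 ± 111 TPM in WT and 952 ± 16.4 in KO at 0 h, a change of 0.38 ± 0.08 (adjusted p = 0.00507). It rose over 8 h by 0.38 ± 0.08 in WT and 0.75 ± 0.08 in KO. Its difference of 0.37 ± 0.12 (adjusted p = 0.0454) lost its call in 16 of 24 alternatives (range 0.000868 to 0.544). The estimate was 0.11 with median-ratio scaling, 0.07 with housekeeping scaling, 0.16 with the length trend removed and 0.22 without WT 0 h replicate 2, so its size is uncertain. Without WT 0 h replicate 1 the changes of Ybx1 at 0 h and over 8 h in WT were 0.23 and 0.22. Slopes of Tet2 (adjusted p = 0.976), Tspan13 (0.564), Cxcr4 (0.973) and Ybx1 (0.561) did not differ past the threshold. At 4 h none of the 4 differed between genotypes past the threshold in its change, with adjusted p of 0.609 for Tet2, 0.95 for Tspan13, 0.228 for Cxcr4 and 0.252 for Ybx1. The 4 h difference of Ybx1, -0.30, was -0.14 without WT 0 h replicate 1 but did pass with median-ratio scaling (-0.38, adjusted p = 0.0391), housekeeping scaling (-0.38, 0.0356) and without WT 0 h replicate 2 (-0.45, 0.0264), in a range of 0.0264 to 0.509. Tet2 fell by 1.13 ± 0.13 in WT and fell by 1.04 ± 0.13 in KO over 8 h, but had 0.41 and 0.21 after median-ratio scaling, and its 8 h difference had an adjusted p of 0.772. All 4 genes are protein coding and on the minus strand, Tspan13 on chromosome 12 (36014557 to 36042500), Cxcr4 on chromosome 1 (128588199 to 128592293) and Ybx1 on chromosome 4 (119277981 to 119294604).

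**Figure D3:**
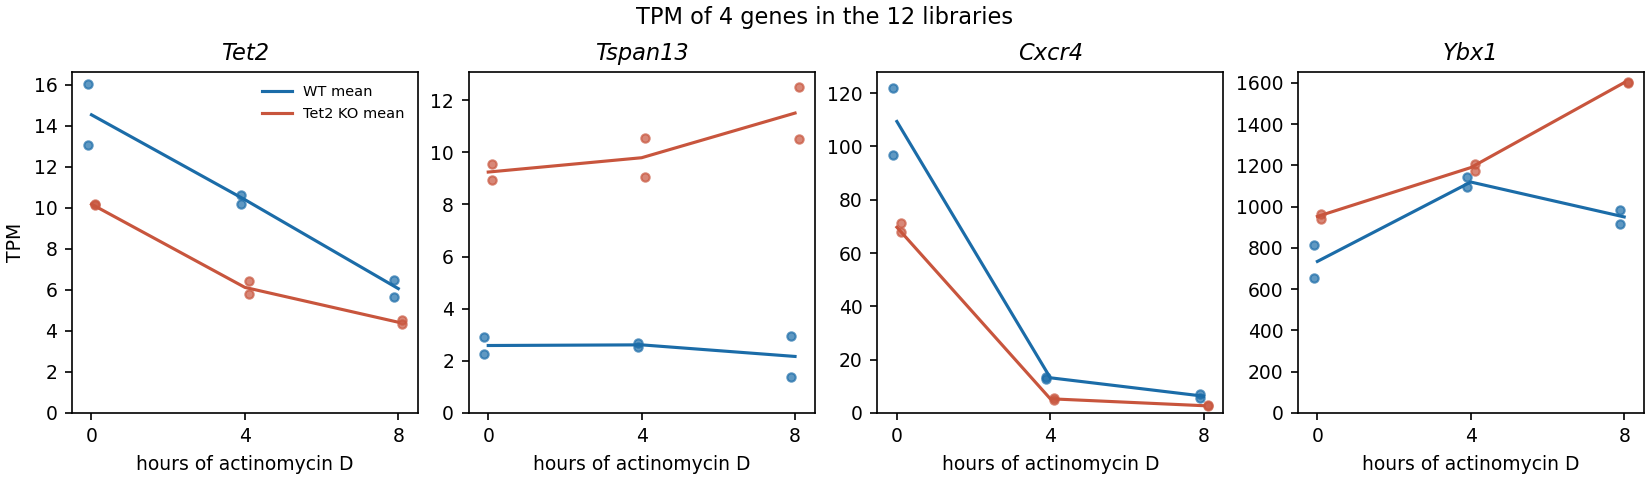
Points are TPM of Tet2, Tspan13, Cxcr4 and Ybx1 in the 12 libraries against hours of actinomycin D, and lines join the means of the 2 libraries of a group. Tspan13 had 2.59 TPM in WT and 9.24 in KO at 0 h, and Cxcr4 dropped in WT from 109 to 6.25 TPM by 8 h.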

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

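The tests of scaling and of transcript length for the 8 h split, of length between the WT 0 h libraries and of a mature cell type were chosen after the results were seen. What brought the following results here is the test of the difference between genotypes in the change after actinomycin D. It passed for 39 genes at 4 h and 2222 genes at 8 h. At 4 h the named genes were Znfx1 at 1.13, Hspa8 at 0.69, Socs1 at -1.83, Id1 at -1.49 and Ddit4 at -1.46 on the log2 scale. At 8 h they were Cox4i2 and Tmem176a, each at 1.62, Oaz1-ps at 1.58, Hist2h3b at -3.48 and Ybx1 at 0.37, which was 0.11 and 0.07 with the 2 scalings. Atp6v0c-ps2 with 1073 TPM and Rab26os with 16.9 TPM in WT at 8 h were listed at 0 in both KO libraries.

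Of the 2222 genes 1929 were higher in KO, a skew for which the libraries' scaling, transcript length and a few abundant transcripts were weighed against a general difference in transcript loss between genotypes. Among transcripts of at least 1000 nt 88.2% of calls were higher. Shorter genes had lower median differences, -0.218 under 600 nt and 0.101 from 600 to 1000 nt. Leaving them out could hardly lower that share, so it does not decide on length. Without the 100 most abundant genes 80.9% were higher, with 1728 higher and 407 lower, which argues against those genes as the whole source. After median-ratio scaling 52.4% were higher and with the length trend removed 61.9%, but both centre the libraries and so nearly fix that share, and the rule for reading the scaling test was revised after its value was seen. Scaling and a general difference in loss cannot be told apart, because TPM hold no absolute amount. An RNA standard added per cell would be needed.

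Transcripts under 600 nt gained share by 8 h, with a median log2 change of 0.43 in WT and 0.12 in KO, so relative to longer genes they had less in KO, by a median gap of -0.40 between 239 short and 10614 longer genes. Such a gap also lay between the WT 0 h libraries, at 0.25, and the WT 8 h libraries, at 0.142, where no genotype differs, so a length bias between libraries may contribute. The 4 other pairs of libraries had gaps of -0.035 to -0.015, so such a bias within groups was not general. A length bias shared by both libraries of a group would not show in these gaps. Without WT 0 h replicate 1 the gap was -0.475. Short genes were higher in that library than in replicate 2, so its removal could only deepen the gap. It therefore does not decide whether a single library is the source, and leaving out WT 0 h replicate 2 was not tested for this gap. A difference between genotypes in the loss of short transcripts stays open and was not tested apart from this, and their median of 0.23 for KO against WT at 0 h enters the 8 h difference.

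Interferon-stimulated and myeloid differentiation genes were lower in KO at 0 h. After median-ratio scaling 30 of 36 interferon-stimulated genes were lower. That count could hardly change, as the log2 factors were 0.771 and 0.959 in the WT 0 h libraries and 0.894 and 0.874 in the KO 0 h libraries. Factors this alike argue against scaling as the source of the interferon-stimulated list median of -1.39. A lower share of 1 mature cell type would lower its genes by a like factor, yet the interquartile range of the 61 called genes was 7.71 times their median standard error. That limit was wrong, because genes that the other cells also express would fall less, and 46 of the 61 had at least 5 TPM in KO at 0 h, so the rule for reading this test was also revised after its value was seen. Cell composition and an effect of genotype within cells therefore cannot be told apart with RNA of whole cultures.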

How the results depend on the processing

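The robust spread, the removal of a trend on transcript length and the limit of 1000 nt were chosen after the data were seen, and the rest were planned. The totals at 8 h in WT and the totals not named here stayed within 1.5 times, while their directions moved, as with 946 higher and 8944 lower at 8 h in WT against 4247 and 4502 after median-ratio scaling. A library left alone in its group was assumed to vary like the other groups. Requiring a 2-fold change as well left 527 genes for KO against WT at 0 h, 4799 for WT at 4 h, 4344 and 6303 for KO at 4 and 8 h, and 22 and 275 for the differences at 4 and 8 h, by its construction. The balance moved too, to 168 higher and 359 lower at 0 h and 166 and 109 for the 8 h difference. The 4 h difference of 39 genes became 162 with median-ratio scaling, 123 with housekeeping scaling, 136 with only the compared groups, 65 with a robust spread, 244 with the length trend removed and 103 with transcripts of at least 1000 nt. The slope difference of 0 genes became 1 with median-ratio scaling, 26 with no filter, 32 with a mean of at least 5 TPM, 33 with a pseudocount of 0.5 and 30 with transcripts of at least 1000 nt. For these the cause was not tested. Camera called 7, 12 and 6 lists for KO against WT at 0 h, WT at 8 h and the slopes, against 3, 3 and 0 with an estimated correlation, and 11 at 0 h and 11 for slopes with no filter. The estimate for Tet2 over time turned positive with median-ratio scaling, past the threshold in WT (0.487 and 0.413 at 4 and 8 h) but not in KO (0.17 and 0.212), since that scaling sets the typical loss to about 0. With 1 library left out, the count at 0 h ranged from 1678 to 3086, the 4 h difference from 9 to 98, the 8 h difference from 1203 to 2727 and the slope difference from 0 to 288. The lists ranged from 6 to 8 at 0 h and from 5 to 9 for slopes, and stayed at 12 at 8 h in WT. The 4 h difference was 19 and 98 without WT 0 h replicate 1 and 2, 24 and 14 without WT 4 h replicate 1 and 2, 10 and 9 without KO 0 h replicate 1 and 2, and 14 and 13 without KO 4 h replicate 1 and 2. The slope count was 288 without WT 0 h replicate 1. At 0 h it was 1703 and 1678 without KO 0 h replicate 1 and 2. The 8 h difference was 1409 without WT 0 h replicate 2, and 1323 and 1203 without KO 0 h replicate 1 and 2. With the replicate number as a block the counts were 2801 at 0 h, 8633 and 9879 in WT, 8080 and 9458 in KO, 40 and 2083 for the differences and 0 for the slopes, and 6, 12 and 6 lists. No pairing by replicate number was seen, as over 15 pairs of groups the replicate differences correlated across genes at -0.083 to 0.051. A small effect shared by libraries of the same number is not excluded. Depth is unknown, so what it limits could not be measured.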

Other observations

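The gene lists of the next sentences and the test of AUUUA pentamers were chosen after the results were seen. Genes of the lysosome were lower in KO at 0 h in 21 of 24, with a median log2 change of -0.51, and after 8 h of actinomycin D were higher in 23 of 24 in WT and 24 of 24 in KO. MHC class II genes were lower in KO at 0 h in 6 of 7 and higher after 8 h in 6 of 7 in WT and 7 of 7 in KO. Schlafen genes were lower in KO at 0 h in 7 of 7, with a median of -1.37, and lower after 8 h in 7 of 7 in each genotype. These directions held with median-ratio and with housekeeping scaling. The 8 h difference between genotypes for the lysosome list depended on scaling. It was lower in KO in 3 of 24 genes as deposited, 21 with median-ratio and 20 with housekeeping scaling, and higher in 0. Hosts of snoRNAs were higher in KO at 0 h in 4 of 13, and after 8 h in WT 3 were higher and 5 lower, which turned to 9 higher and 2 lower with median-ratio scaling. The noncoding Malat1 had 434 ± 6.55 TPM (SD, n = 2) at 4 h and 962 ± 51.9 at 8 h in WT cells. As a share of the library it can rise while other transcripts are lost, and its change from 0 h is not given.

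Whether relative stability adds to the baseline difference was tested on libraries that the measures do not share. Across 7871 genes, which are not independent replicates, the KO minus WT change at 0 h and the KO minus WT change from 4 to 8 h had a Spearman rho of 0.131 and a Pearson r of 0.094. This small positive relation is consistent with a minor contribution of stability, as a hypothesis, and the share of baseline differences that it explains would be small.

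Genes with more AUUUA pentamers per kb of 3' UTR, a motif of unstable mRNA, had a lower change at 8 h in WT, with a Spearman rho of -0.145 across 10367 genes, and -0.158 in KO. The median log2 change was -1.07 in the lowest and -1.60 in the highest quartile. With transcript length held fixed the rho was -0.075 in WT and -0.089 in KO, and with the AU content of the 3' UTR also held fixed -0.003 and -0.011. An effect of the motif on loss therefore cannot be told apart from transcript length and AU content, which includes the motif itself, and the rule for reading this test was revised after these values were seen.

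Splits of the libraries within each time do not decide on the slope difference. The real split had 0 genes, which cannot be undercut, so all 100 drawn splits had as many, and another split had up to 1932. A split that mixes the genotypes turns their baseline difference into a slope difference, so these counts point to a structure of the samples. For the gene lists, with 6 in the real split, up to 11 in another and as many in 43, the same holds, and chance is neither shown nor excluded.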
